A study of Mus musculus with 21 samples.

How the data were processed

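Gene expression was measured in dendritic cells grown from the bone marrow of C57Bl6 mice, with 1 Illumina mouse bead array for each of 21 samples. Per the labels' protocols, total RNA was extracted on columns, its quality was checked by capillary electrophoresis, and biotin-labelled cRNA was hybridised to the arrays. The samples cover 3 genotypes, namely wild type (WT), relb-/- and crel-/-relb-/-. Relb encodes RelB, the NF-kB subunit best known from the non-canonical pathway, and Rel encodes c-Rel, a subunit of the canonical pathway. Each genotype was measured in 7 conditions: unstimulated at 0 h, and after 1, 8 and 24 h with CpG, a DNA ligand of TLR9, or with Pam3CSK4, a lipopeptide ligand of TLR2 with TLR1. Each genotype in each condition has 1 array, so no condition has a replicate. Groups were taken from the sample labels alone.

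The values analysed are the authors' deposited normalized probe intensities on a linear scale, 25697 probes on each array. The intensity medians of the 21 arrays lay between 47.1 and 47.4 and their quartiles were nearly equal, which shows that the authors had normalized the arrays to each other. The normalization method is not given in the sources used here. The background was not subtracted from these intensities, so fold changes of dim genes are understated. No 2 arrays held identical values. A second deposited table of unnormalized signals was not used, because the names of its 21 columns match no sample's labels. The analysis fixed before the data were examined had planned a normexp background correction with an offset of 50 and quantile normalization of unnormalized signals. As only the normalized table could be tied to samples, log2 of the authors' deposited intensities was analysed without further normalization, and the planned treatment was applied to them as an added alternative. No detection p-values were used, so the only measure of signal over background was the brightness of a probe relative to the median of all values, 47.3.

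Probes were named through the platform's annotation table, with symbols updated by Entrez identifier for 23962 probes through a table of RefSeq genes. Of all probes, 23978 had 1 gene symbol, 0 had several, and 1719 were not listed and stay unnamed here. The genome build behind the probes is not given in the sources used here, so no coordinates are printed, and the table of genes was used only for names and for which genes neighbour each other. A probe entered the tests when the 3rd highest of its 21 log2 values lay above the median of all values. Each gene was represented by its passing probe with the highest mean. This left 10587 of 16593 named genes, or 63.8%. For 2775 genes with several passing probes, the number whose probes were called in opposite directions was 2, 5 and 6 in the 3 comparisons of genotypes, 0, 9 and 18 at 1, 8 and 24 h, and 0 between the agents.

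All tests were run with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called at an adjusted p under 0.05. All limma tests were two-sided. There were 12 comparisons across all genes. The genotype, time and agent comparisons came from 1 additive model of genotype and condition on all 21 arrays, with 12 residual degrees of freedom. Genotypes were compared within 7 conditions. Each time was compared with 0 h over 6 combinations of genotype and agent, which share the 3 arrays at 0 h between the agents and are not independent, and the agents over 9 combinations of genotype and time. Differences in late response between genotypes came from a model with an interaction of genotype and late time, where 8 and 24 h counted as late (4 arrays per genotype) and 0 and 1 h as early (3 arrays per genotype), with 10 residual degrees of freedom. Differences between agents in the genotype effect came from the 18 stimulated arrays, with 8 residual degrees of freedom. The residual spread in all of these models holds the variation of an effect between conditions. The labels do not say whether arrays of 1 genotype came from separate cultures or animals, so the p-values measure how constant a difference was over these conditions and not its spread between animals. No difference within a single condition was tested. The number of arrays limits the precision.

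The induction of late-induced genes as a set was compared with an exact two-sided permutation test that swapped the genotype labels within conditions (128 assignments, smallest possible p 0.015625). Late-induced genes had an adjusted p under 0.05 and a log2 rise of at least 1 from early to late times over all genotypes. Gene lists fixed before the data were examined were tested with camera in limma, with the preset correlation of 0.01 and again with an estimated correlation, adjusted over the 22 lists with at least 5 tested members. The 14 pathway lists were the NF-kB family and its inhibitors, cytokines, chemokines, dendritic cell maturation and costimulation, MHC class II presentation, MHC class I presentation, interferon-stimulated genes, immediate-early genes, inflammatory effectors, cell cycle, cholesterol biosynthesis, glycolysis and hypoxia, oxidative phosphorylation, and heat shock and the unfolded protein response. The 11 cell type lists held markers of conventional and plasmacytoid dendritic cells, macrophages and monocytes, neutrophils, B cells, T and natural killer cells, mast cells and basophils, eosinophils, erythroid cells, stromal cells and Langerhans-like or migratory cells. A further list held genes that report the sex of the animals. Of 420 symbols written, 377 matched the array.

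The genes named were set by a rule fixed in advance. Besides Relb and Rel, it took the 12 largest called rises and falls of each genotype comparison that went the same way in all 7 conditions, and the 8 largest at each time that went the same way in all 6 combinations. It took the 10 largest in each direction for late responses, and the 8 largest between agents with the same sign in at least 8 of 9 combinations. For each list it took up to 4 called members in each direction, or the 2 largest where none was called. Unnamed gene models were left out.

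The models were tested on simulated data with 10587 genes, of which 200 were changed by known amounts. A log2 change of 0.5 was recovered for 99% of changed genes between relb-/- and WT, 88% at 1 h, 91% at 8 h, 41% for late responses between relb-/- and WT, 100% between the agents and 34% for the interaction of relb-/- with the agent. For a log2 change of 1 these shares were 100%, 100%, 100%, 96%, 100% and 92%. False calls made up 7.01%, 3.59%, 2.05%, 4.20%, 3.38% and 3.08% of calls in the same order. The simulated noise was independent between arrays, with no effect shared by the arrays of a culture or animal. These shares therefore leave out false calls from such an effect.

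Alternatives planned in advance were an offset of 16 with quantile normalization, cyclic loess, median scaling, no filter, a stricter filter, every probe, robust variances, array weights, a 2-fold threshold, each condition or genotype left out in turn, only the groups compared, and other definitions of early and late. The authors' processed values, planned as an alternative, became the main values. A block for chip or scan date was not run, because the sources used here give neither. The normexp treatment, the removal of 1 array that stood apart, a set of late-repressed genes, a second permutation of conditions and exact swap tests of the means of 12 lists were added after the data were seen. Those 12 lists were chosen at that point too, and the adjustment over the swap tests does not account for that choice. Numbers after a ± sign are standard errors from the limma fit unless an SD is named, and log2 changes are differences of log2 intensity.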

Results

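Bone marrow-derived dendritic cells are antigen-presenting cells grown from marrow progenitors in culture. The 21 arrays compared WT, relb-/- and crel-/-relb-/- cells, each unstimulated and after 1, 8 and 24 h with CpG or Pam3CSK4, with 7 arrays per genotype and 1 array per genotype and condition. The design asks how the transcriptome of dendritic cells, at rest and after activation through Toll-like receptors, depends on RelB and on c-Rel. In a principal component analysis of the 10587 genes tested, the first component held 49.0% of the variance and separated the arrays at 8 and 24 h from those at 0 and 1 h, and the second held 13.6% and varied with both time and genotype. On the second component the relb-/- array lay lowest and the crel-/-relb-/- array highest in 7 of 7 conditions, while the ranges of the genotypes over all conditions overlapped. The crel-/-relb-/- array at 24 h with CpG stood apart from the others. Its residual SD was 0.189 on the log2 scale, and those of the other 20 arrays lay between 0.0966 and 0.141.

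The targeted genes were read first. The Relb probe had a mean intensity of 208 ± 44.2 in WT, 109 ± 31.6 in relb-/- and 114 ± 44.8 in crel-/-relb-/- cells (SD, n = 7 each). The log2 difference from WT was -0.97 ± 0.11 in relb-/- (adjusted p = 3.47e-06) and -0.94 ± 0.11 in crel-/-relb-/- cells (adjusted p = 2.72e-06), lower in 7 of 7 conditions in both. The Rel probe had a mean intensity of 117 ± 46.5 in WT, 127 ± 39.7 in relb-/- and 38.0 ± 3.91 in crel-/-relb-/- cells (SD, n = 7 each). Its difference from WT was 0.16 ± 0.15 in relb-/- (adjusted p = 0.550) and -1.53 ± 0.15 in crel-/-relb-/- cells (adjusted p = 3.70e-07). On every crel-/-relb-/- array the Rel probe lay between 33.6 and 45.5, below the median of all values. The Relb probe stayed above that median on every knockout array. Where these probes lie relative to the disrupted part of each gene is not given in the sources used here, and a probe outside that part checks nothing.

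**Figure D1:**
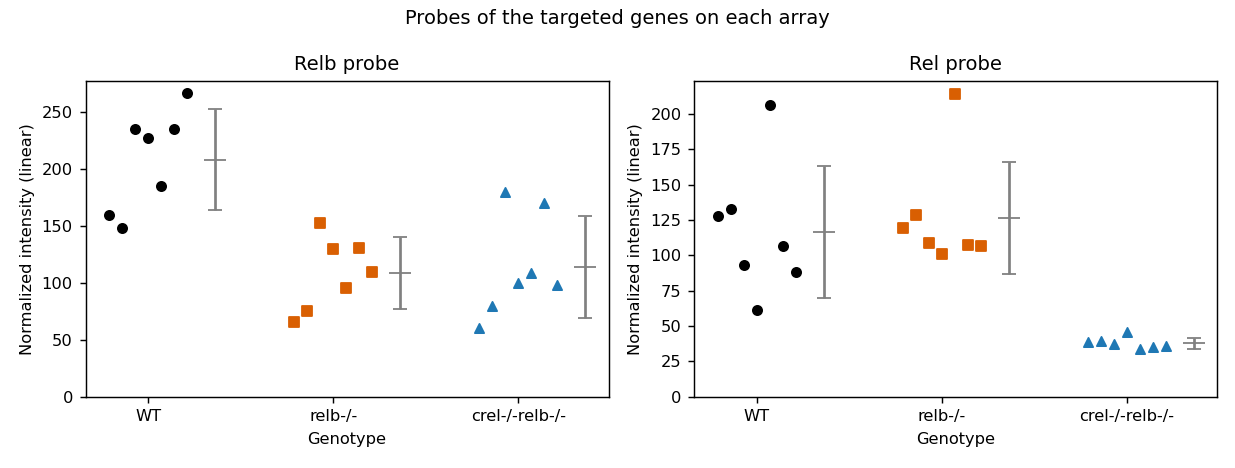
Normalized intensity of the Relb and Rel probes on each of the 21 arrays, by genotype, with each genotype's mean intensity and its SD (n = 7). The Relb probe was lower in both knockout genotypes than in WT, and the Rel probe lay between 33.6 and 45.5 in crel-/-relb-/- cells.

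The relb-/- cells expressed more of the interferon-β gene and of interferon-stimulated genes as a list than WT cells, at rest and in each stimulated condition. In crel-/-relb-/- cells the mean of that list was above WT in only 2 of 7 conditions, at 8 h (0.70) and 24 h (0.865) with CpG, the latter from the array that stood apart. The comparison of relb-/- with WT is made within conditions and averaged over them, and it holds any other difference between the cultures or animals of these genotypes as well. Among antiviral effectors, the log2 difference was 2.59 ± 0.45 for Ifit3 (adjusted p = 5.98e-04), 2.51 ± 0.30 for Oasl1 (adjusted p = 8.50e-06) and 2.35 ± 0.40 for Rsad2, which encodes viperin. Ifnb1, the interferon-β gene, was higher by 1.99 ± 0.24 (adjusted p = 8.76e-06), with intensities of 96.9 to 487 in relb-/- cells against 34.6 to 51.9 in WT cells, close to the median of all values, so that its fold is understated. Cxcl1, a neutrophil chemoattractant, was higher by 1.89 ± 0.18 (adjusted p = 3.92e-07). Each of these genes was higher in 7 of 7 conditions. The other genes named by the rule as higher were Ifit2 (2.25), the ubiquitin-like modifier Isg15 (2.22), Crxos (2.08), Phf11a (2.05), Ifi27l2a (1.94), Cmpk2 (1.85) and Usp18 (1.63).

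The genes with the largest decreases in relb-/- against WT cells included Clu, C1qb, C1qc and the T cell genes Cd3d, Cd3g and Trat1. Clu, which encodes the secreted chaperone clusterin, had a log2 difference of -1.69 ± 0.10 (adjusted p = 3.13e-10). The complement C1q subunits C1qb and C1qc differed by -1.42 and -1.38, and Il4i1, a secreted amino acid oxidase, by -1.38. The CD3 subunits Cd3d and Cd3g differed by -1.27 and -1.22, the T cell receptor-associated adaptor Trat1 by -1.33, and Nkg7, found in cytotoxic granules, by -1.35. Slc4a8, the thrombin receptor F2r, the chromatin organiser Satb1 and Dmrta2 differed by -1.41 to -1.21. In all, 1236 genes differed between relb-/- and WT (638 higher, 598 lower), and 53 of them by at least 2-fold (33 higher, 20 lower).

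Of the 25 interferon-stimulated genes tested, 23 were called higher in relb-/- cells, none lower and 2 not called, with a median log2 difference of 1.08. Adjusted over the list alone, 24 were higher. Camera placed the list above other genes (adjusted p = 2.42e-20), a call that was lost at an adjusted p = 0.153 with an estimated correlation. The mean difference of the list was above 0 in 7 of 7 conditions and ranged from 0.32 at 8 h with CpG to 2.02 at 24 h with Pam3CSK4. Swapping genotypes within conditions gave an exact permutation p = 0.015625, the smallest possible (two-sided; adjusted p = 0.0225 over 36 such tests of lists). Of 12 lists given this test, chosen after the data were seen, 8 had that same p between relb-/- and WT. Cytokines, chemokines and MHC class I genes were the others higher, and MHC class II, cholesterol biosynthesis, macrophage and T and natural killer cell lists were lower. The test asks whether a list's mean differs from 0 in a constant direction, and not whether it differs from other genes, so that cholesterol biosynthesis passed it with a mean of only -0.10. Plasmacytoid dendritic cell markers, whose cell type is a major source of interferon, had no called member of 6 (2 higher and 1 lower adjusted over the list alone) and a camera adjusted p = 0.543. The 2 with the largest differences were Bst2 (0.58) and Tcf4 (0.31).

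Several other groups shifted between relb-/- and WT in part of their members. Of 18 cytokine genes, 6 were higher and none lower (6 higher and 1 lower over the list alone), led by Ifnb1, Tnfsf15 (0.73), Il15 (0.69) and Ebi3 (0.54). The camera adjusted p = 0.00251 became an adjusted p = 0.359 with an estimated correlation. Of 17 chemokine genes, 4 were higher, among them Cxcl1, Cxcl10 (0.95) and Cxcl3 (0.44), and Cxcl9 was lower (-0.49). Adjusted over the list alone 8 were higher and 2 lower, and the camera adjusted p = 0.0077 became an adjusted p = 0.153 with an estimated correlation. Of 16 immediate-early genes, which encode transcription factors and phosphatases induced within minutes, 5 were higher, such as Fos (0.57), Atf3 (0.55) and Egr1 (0.53), or 7 adjusted over the list alone. That list had a camera adjusted p = 0.00562, and an adjusted p = 0.385 with an estimated correlation. Of 16 MHC class I genes, 2 were higher, namely H2-D1 (0.55) and Psme1 (0.22), or 3 adjusted over the list alone. The camera adjusted p = 0.0077 rose to an adjusted p = 0.418 with an estimated correlation.

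MHC class II genes went the other way. Of 12 tested, 5 were lower and none higher in relb-/- cells, including H2-DMb2 (-0.64), H2-Ab1 (-0.48), H2-Eb1 (-0.44) and the invariant chain gene Cd74 (-0.36). Adjusted over the list alone 7 were lower, and the camera adjusted p = 1.27e-04 became an adjusted p = 0.133 with an estimated correlation. Maturation and costimulation genes moved both ways. Cd40 (1.33), Cd80 (0.82), Cd70 (0.56) and Cd86 (0.53), all costimulatory molecules, were among 7 of 23 called higher. Il4i1, Marcksl1 (-0.57), Fscn1 (-0.56) and H2-M2 (-0.30) were the 4 called lower. Adjusted over the list alone these counts were 11 and 5, and the camera adjusted p was 0.0675. The NF-kB list had 3 of 14 higher by either adjustment, namely Tnfaip3 (0.51), Map3k14 (0.50) and Nfkbib (0.29), with a camera adjusted p = 0.113.

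Markers of other cell types moved beside these groups. Of 7 T and natural killer cell markers, 5 were lower and 1, Klrd1 (0.34), was higher in relb-/- cells (median -0.54), or 5 lower and 2 higher adjusted over the list alone. Their camera adjusted p = 7.36e-05 became an adjusted p = 0.153 with an estimated correlation. Of 12 macrophage and monocyte markers, 5 were lower, among them C1qb, C1qc and Mrc1 (-0.60), and Fcgr1 (0.45) and Adgre1 (0.28) were higher. Adjusted over the list alone 6 were lower, and the camera adjusted p = 0.00562 became an adjusted p = 0.130 with an estimated correlation. The conventional dendritic cell list had 1 of 11 lower, Irf8 (-0.88), a transcription factor of that lineage, with a camera adjusted p = 0.460. The neutrophil list had 4 of 12 higher, led by S100a9 (0.86) and S100a8 (0.75), and 2 lower (adjusted p = 0.356), with 5 higher adjusted over the list alone. No camera call between relb-/- and WT held with an estimated correlation.

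Camera called none of the remaining lists between relb-/- and WT. Camera adjusted p-values were 0.649 for inflammatory effectors (3 of 21 lower), 0.057 for cell cycle genes (2 of 20 higher, 6 lower), 0.057 for cholesterol biosynthesis (none of 14 called) and 0.818 for glycolysis and hypoxia (1 higher and 1 lower of 16). They were 0.879 for oxidative phosphorylation, 0.649 for heat shock and the unfolded protein response (1 of 13 lower), 0.116 for B cell, 0.852 for eosinophil and 0.356 for stromal markers. Over the list alone no heat shock gene was called, and the counts of the 4 pathway lists named first were the same. Of 16 oxidative phosphorylation genes, 1 was higher (0 adjusted over the list alone), and the list's median of -0.02 opposed its mean of 0.02. None of 5 B cell, 6 stromal or 2 Langerhans-like markers was called by either adjustment. Of 5 eosinophil markers 1 was higher (1 higher and 1 lower over the list alone), of 4 mast cell and basophil markers 1 was lower (2 over the list alone), and of 4 erythroid markers 1, Car2 (0.85), was higher (2 over the list alone). Of the genes that report sex, 2 were tested and neither was called between any 2 genotypes.

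**Figure D2:**
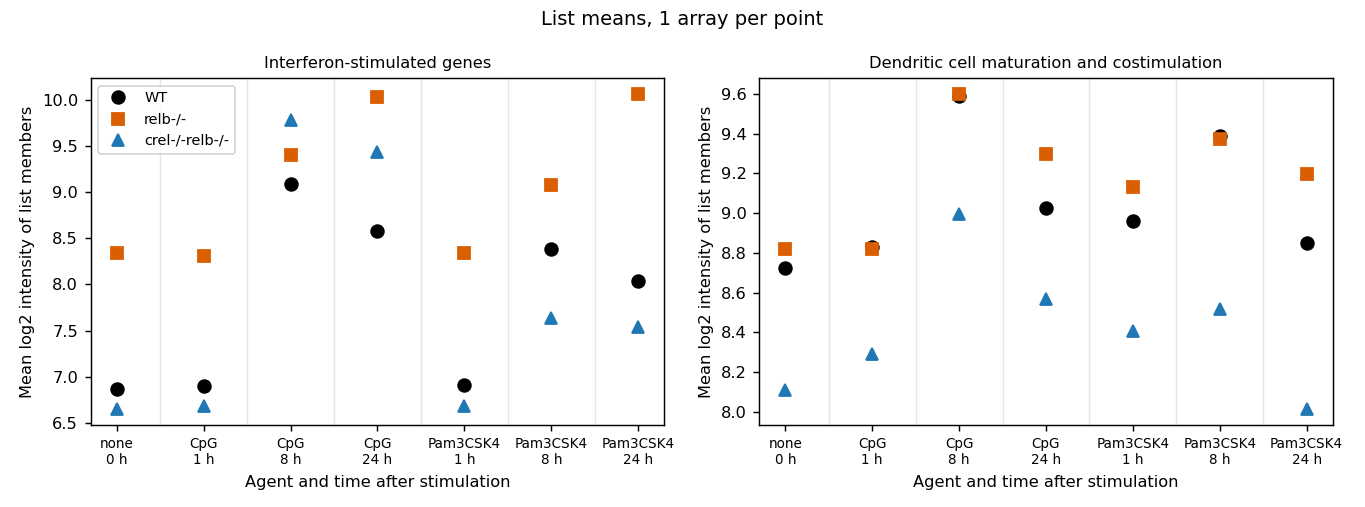
Means over the members of selected gene lists, on the log2 scale, in each of the 7 conditions (horizontal axis), by genotype, with 1 array per point. The interferon-stimulated list lay above WT in 7 of 7 conditions in relb-/- cells and in 2 of 7 in crel-/-relb-/- cells.

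Cells without both c-Rel and RelB had lower levels of genes of mature dendritic cells than WT cells. Fscn1, the actin-bundling protein fascin of mature dendritic cells, had a log2 difference from WT of -4.04 ± 0.12 (adjusted p = 4.62e-15), a 16.5-fold lower intensity. Apol7c differed by -2.59 ± 0.23 (adjusted p = 9.00e-08), Marcksl1 by -2.29 ± 0.15 (adjusted p = 1.72e-09) and Clu by -2.30 ± 0.10 (adjusted p = 1.21e-12). Cd40, the receptor through which T cells license dendritic cells, differed by -1.55 ± 0.23 (adjusted p = 7.22e-05). Of its 3 other probes, 2 were also lower (-1.28 and -0.47), and the third gave -0.15 (adjusted p = 0.337). Each of these genes was lower in 7 of 7 conditions. Stat4, which carries the interleukin-12 signal, differed by -1.62, though 1 of its other probes gave -0.06 (adjusted p = 0.367). The other genes named as lower were Ogfrl1 (-1.91), Grasp (-1.75), Tcaf2 (-1.59), Rel (-1.53), Serpinb6b (-1.53) and the protease gene Ctsc (-1.46).

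Some transcripts of granulocytes and that of an Fc receptor were higher in crel-/-relb-/- than in WT cells. S100a9 and S100a8, which form calprotectin, were higher by 1.93 ± 0.16 and 1.5 ± 0.15, and Prg2, the eosinophil major basic protein, by 1.07 ± 0.10 (adjusted p = 3.35e-08, 5.30e-07 and 2.01e-07). Fcgr3, a low-affinity IgG receptor, was higher by 1.51 ± 0.09 (adjusted p = 5.28e-10). Crxos (2.79), the interferon-inducible Ifi202b (2.17), Stfa1 (1.70), Emp1 (1.34), Tmem51 (1.12), Fam181b (1.12), Gpr65 (1.09) and Rbp4 (1.07) were also higher. All were higher in 7 of 7 conditions. In all, 1629 genes differed (810 higher, 819 lower), and 49 of them by at least 2-fold (15 higher, 34 lower).

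Of the 23 maturation and costimulation genes, 11 were lower in crel-/-relb-/- than in WT cells and 1, Tnfsf4 (0.72), was higher, with a median of -0.30. Adjusted over the list alone 12 were lower and 1 higher. The camera call (adjusted p = 5.24e-09) held with an estimated correlation (adjusted p = 0.0364). The list lay below WT in its mean over conditions with an exact permutation p = 0.015625, the smallest possible (two-sided, n = 7). Of the 12 lists given this test, 7 had that p between crel-/-relb-/- and WT, the T and natural killer cell list among the lower ones and cholesterol biosynthesis, oxidative phosphorylation, macrophage, eosinophil and neutrophil lists higher. Cholesterol biosynthesis genes went up as a group, with 8 of 14 higher and none lower (9 adjusted over the list alone). They included the sterol carrier Stard4 (0.64), Fdps (0.47), Hsd17b7 (0.41) and Insig1 (0.41). Oxidative phosphorylation genes did so as well, with 5 of 16 higher and none lower (7 adjusted over the list alone), including the ATP synthase subunit Atp5a1 (0.56) and the succinate dehydrogenase subunits Sdhc (0.46) and Sdhb (0.39). The camera adjusted p of these 2 lists was 1.76e-06 and 2.04e-04, and 0.0091 for both with an estimated correlation.

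Eosinophil and T cell markers moved beside these groups in crel-/-relb-/- cells. Of 5 eosinophil markers, 2 were higher than in WT by either adjustment, Prg2 and the ribonuclease Ear6 (1.00), with a camera adjusted p = 0.00115 that held with an estimated correlation (adjusted p = 0.0213). Of 7 T and natural killer cell markers, 4 were lower by either adjustment, namely Cd3g (-1.05), Cd3d (-0.88), Nkg7 (-0.74) and Cd3e (-0.33). That camera adjusted p = 1.92e-04 became an adjusted p = 0.134 with an estimated correlation. Of 12 neutrophil markers, 5 were higher, including S100a9, S100a8, Ltf (1.03) and Ngp (0.45), and Lcn2 (-0.29) was lower, the same counts as over the list alone. Their camera adjusted p = 0.0401 became an adjusted p = 0.243 with an estimated correlation and an adjusted p = 0.0704 without the array that stood apart. It was also lost with cyclic loess (0.0503), with an offset of 16 (0.0801) and with normexp (0.0819). Conventional dendritic cell markers went both ways, with Irf8 (-0.90), Irf4 (-0.38), Batf3 (-0.31) and Zbtb46 (-0.23) lower and Cd24a (0.49) and Itgax (0.33) higher (4 and 3 of 11 over the list alone; adjusted p = 0.396).

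The interferon-stimulated list as a whole was not called between crel-/-relb-/- and WT cells. Ifnb1 differed by 0.13 ± 0.24 (adjusted p = 0.781). Of 25 members, 3 guanylate-binding proteins were lower by either adjustment, namely Gbp2 (-1.09), Gbp3 (-1.08) and Gbp5 (-0.83), and none was higher. Its median of 0.10 opposed its mean of -0.05 and the downward camera direction (adjusted p = 0.799). MHC class I genes were lower in 7 of 16 (10 adjusted over the list alone), such as Tapbpl (-0.58), Psmb10 (-0.54), Psmb9 (-0.50) and their transactivator Nlrc5 (-0.48), and H2-D1 was higher (0.36). The camera adjusted p = 0.00313 became an adjusted p = 0.368 with an estimated correlation. Of 18 cytokine genes, 8 were lower, including Il15 (-1.03), Il1b (-0.73), Tnfsf9 (-0.66) and Il23a (-0.59), and Il1rn (0.54) and Lta (0.43) were higher, the same counts as over the list alone (adjusted p = 0.0744). Of 17 chemokine genes, Ccl22 (-1.09) and Cxcl2 (-0.57) were among 4 lower, and Cxcl1 (0.73) and Ccl17 (0.49) were higher, or 4 higher adjusted over the list alone. The chemokine median of 0.17 and mean of 0.03 opposed the downward camera direction (adjusted p = 0.954). Traf1 (-0.78) and Nfkbia (-0.48) were lower and Nfkbid (0.30) higher among 14 genes of the NF-kB list (4 lower and 1 higher over the list alone; adjusted p = 0.0576). B cell markers (median 0.13, mean -0.02, adjusted p = 0.898) and plasmacytoid markers (median 0.04, mean -0.14, adjusted p = 0.548) also differed in sign between median and mean.

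Cells of crel-/-relb-/- and relb-/- genotype both lack RelB and differ in c-Rel, though their difference holds any other one between the cultures or animals too, and c-Rel loss alone was not analysed here. Apol7c (-3.49 ± 0.23, adjusted p = 1.11e-09), Fscn1 (-3.48 ± 0.12, adjusted p = 9.16e-14) and Cd40 (-2.89 ± 0.23, adjusted p = 1.80e-08) had the largest falls, and all 3 other Cd40 probes were lower too. Ifnb1 differed by -1.86 ± 0.24 (adjusted p = 8.89e-06) and Il15, a survival factor for natural killer and memory T cells, by -1.72 ± 0.15 (adjusted p = 9.37e-08). Trim30a (-2.17), Marcksl1 (-1.72), Rel (-1.70), Lad1 (-1.66), Meis1 (-1.54), Sema7a (-1.53) and Gbp3 (-1.53) were also lower. Higher in crel-/-relb-/- cells were Ifi202b (2.30), Fcgr3 (1.5), the decoy receptor Tnfrsf11b (1.48), Fam181b (1.42), C1qc (1.37), Retnla (1.34), C1qb (1.32), Dmrta2 (1.27), the mannose receptor Mrc1 (1.21), Mmp2 (1.19), Stfa1 (1.16) and Rbp4 (1.13). All went the same way in 7 of 7 conditions. In all, 2099 genes differed (1116 higher, 983 lower), and 93 of them by at least 2-fold (20 higher, 73 lower).

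Of the 25 interferon-stimulated genes, 24 were lower in crel-/-relb-/- than in relb-/- cells and none higher, by either adjustment, with a median of -1.20. The camera adjusted p = 5.18e-17 became an adjusted p = 0.122 with an estimated correlation, and the list's mean was lower in 6 of 7 conditions (exact permutation p = 0.03125, two-sided). In this test 11 of 12 lists passed after adjustment between the knockouts, and the T and natural killer cell list did not (exact permutation p = 0.0625). Maturation genes were lower in 16 of 23 and higher in 2 by either adjustment, with Cd86 at -1.11 and a median of -0.63 (adjusted p = 1.28e-12, and 0.0129 with an estimated correlation). Of 18 cytokine genes, 9 were lower (11 lower and 1 higher adjusted over the list alone), and of 16 MHC class I genes, 9 were lower by either adjustment. Their camera adjusted p-values of 1.71e-05 and 1.15e-06 became adjusted p-values of 0.122 and 0.107 with an estimated correlation. Of 14 NF-kB genes, 6 were lower (7 lower and 1 higher adjusted over the list alone), such as Traf1 (-1.02), Tnfaip3 (-0.77) and Nfkbia (-0.68). Of 17 chemokine genes, 4 were lower, led by Ccl22 (-1.36) and Cxcl1 (-1.16), and 2 higher (5 and 2 over the list alone). Camera adjusted p-values of 0.00171 and 0.0145 for these lists became adjusted p-values of 0.129 and 0.123 with an estimated correlation.

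Sterol, respiratory and macrophage genes were higher in crel-/-relb-/- than in relb-/- cells. Of 14 cholesterol biosynthesis genes, 10 were higher and none lower (13 adjusted over the list alone), including Fdps (0.72), Stard4 (0.62), Cyp51 (0.54) and Mvd (0.53), with a camera adjusted p = 4.68e-09. Of 16 oxidative phosphorylation genes, 6 were higher and none lower (7 adjusted over the list alone; adjusted p = 6.68e-04). Of 12 macrophage and monocyte markers, 8 were higher and 1, Fcgr1 (-0.71), lower by either adjustment (adjusted p = 1.19e-05). Of 5 eosinophil markers, 3 were higher by either adjustment (adjusted p = 6.68e-04). With an estimated correlation the adjusted p-values of these 4 lists were 0.0037, 0.0129, 0.00373 and 0.0131. Of 12 MHC class II genes, 6 were higher by either adjustment, led by H2-Eb1 (0.82), H2-Ab1 (0.63), H2-Aa (0.47) and H2-DMb1 (0.40), with an adjusted p = 1.46e-04 and an adjusted p = 0.0589 with an estimated correlation. Of 20 cell cycle genes, 7 were higher and 1 lower (8 and 1 over the list alone), with an adjusted p = 0.00278 and an adjusted p = 0.176 with an estimated correlation. Median, mean and camera direction differed in sign for conventional dendritic cell markers (0.10, 0.03, downward, adjusted p = 0.944), inflammatory effectors (0.03, -0.02, downward, 0.848) and heat shock genes (-0.04, -0.01, upward, 0.944).

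**Figure D3:**
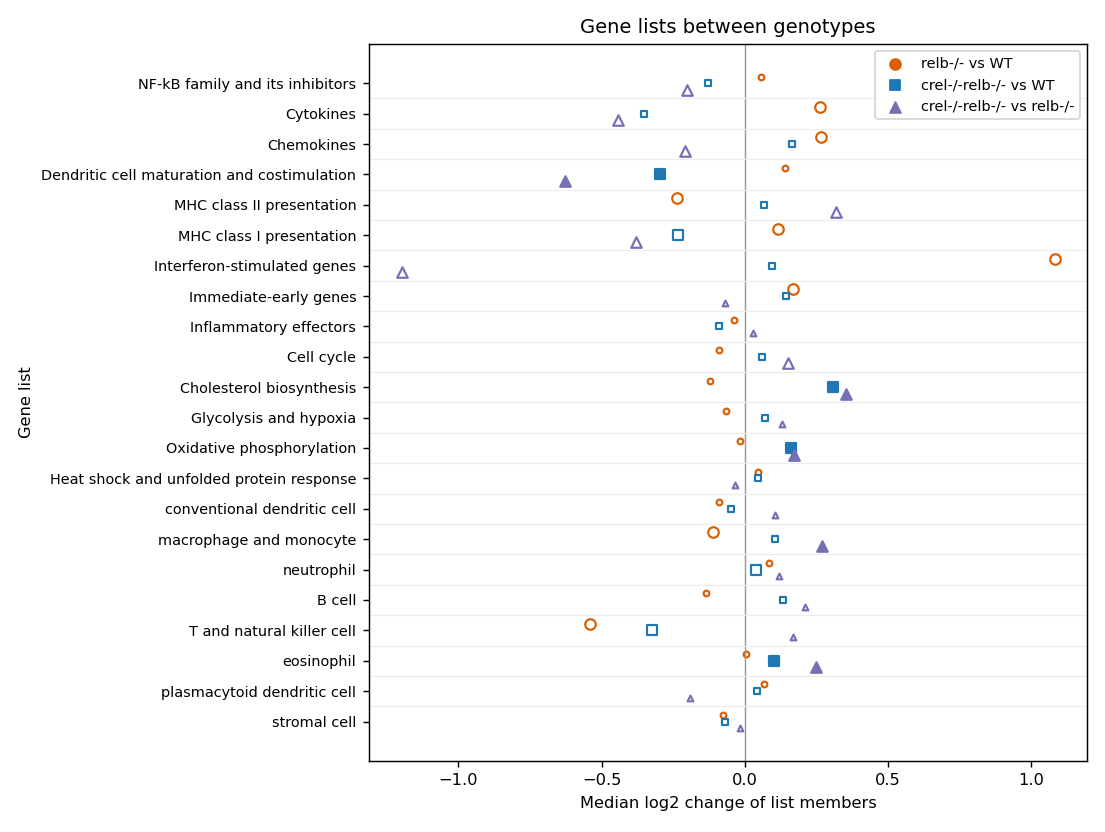
Median log2 change of each gene list (vertical axis) in each comparison shown, where a large marker is a list called by camera with the preset correlation and a filled one was also called with an estimated correlation. Interferon-stimulated genes had medians of 1.08 in relb-/- against WT and -1.20 in crel-/-relb-/- against relb-/- cells.

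Stimulation changed few genes by 1 h and many more by 8 and 24 h, as averages over the 3 genotypes and both agents. At 1 h the cytokine gene Tnf rose by 4.67 ± 0.31 (adjusted p = 3.49e-09) and Nfkbiz, an atypical inhibitor of the NF-kB family, by 4.59 ± 0.11 (adjusted p = 6.97e-17). The chemokines Cxcl1 and Cxcl2 rose by 3.24 ± 0.23 and 2.75 ± 0.17 as averages of unlike agents, Cxcl1 by 4.93 ± 0.37 with Pam3CSK4 and 1.55 ± 1.02 with CpG, and Cxcl2 by 4.54 ± 0.35 and 0.96 ± 0.24 (SD, n = 3, no test). Socs3 (2.53), Nfkbid (2.41), the NF-kB inhibitor Tnfaip3 (2.34) and the phosphatase Dusp2 (2.26) followed. Dusp6, an ERK phosphatase, was lower (-1.19 ± 0.14, adjusted p = 2.40e-05), though 1 of its 2 other probes gave -0.19 (adjusted p = 0.240). Plekhf1 (-0.98), Nfil3 (-0.97), Cass4 (-0.79), Nfe2 (-0.79), Hhex (-0.64) and Hs3st1 (-0.64) were lower as well, and all went the same way in 6 of 6 combinations of genotype and agent. In all, 118 genes changed at 1 h (88 higher, 30 lower), and 32 of them by at least 2-fold (31 higher, 1 lower). The count was 30 without WT arrays, 49 without relb-/- arrays and 71 without crel-/-relb-/- arrays, but 183 without the array that stood apart, 261 with array weights and 362 on the 9 arrays compared alone. Nfe2 (adjusted p = 0.0783), Hhex (0.160) and Hs3st1 (0.143) lost their calls without WT, Cass4 (0.0841) and Hhex (0.423) without relb-/-, and Nfe2 (0.0698) without crel-/-relb-/- arrays.

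The NF-kB list led the response at 1 h, with 6 of 14 genes higher (7 adjusted over the list alone), an adjusted p = 9.15e-23 and an adjusted p = 0.00108 with an estimated correlation. Of 16 immediate-early genes, 7 were higher (8 adjusted over the list alone), including Dusp2, Egr1 (1.67), Zfp36 (1.56) and Dusp1 (1.23). Of 18 cytokine genes, 6 were higher (7 adjusted over the list alone), including Il6 (1.65), Il1a (1.28) and Il23a (1.21). These averages hide a difference between the agents, since Il1a changed by 2.85 ± 0.76 with Pam3CSK4 and by -0.28 ± 0.29 with CpG, and Il6 by 2.64 ± 0.09 and 0.66 ± 0.13 (SD, n = 3, no test). Camera adjusted p-values of 6.23e-12 and 8.09e-10 for these lists became adjusted p-values of 0.0577 and 0.0707 with an estimated correlation. Of 17 chemokine genes, 2 were higher by either adjustment, and of 23 maturation genes 1 was higher, or 5 adjusted over the list alone. Their camera adjusted p-values of 0.00315 and 5.27e-04 became adjusted p-values of 0.107 and 0.285 with an estimated correlation. Glycolysis and hypoxia genes had none of 16 called and a median of -0.11, with a camera adjusted p = 0.00876 and an adjusted p = 0.526 with an estimated correlation.

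At 8 h the genes with the largest rises were Cxcl5, Ppbp and Cxcl1, all chemokines. Cxcl5 was higher by 5.71 ± 0.20 (adjusted p = 9.40e-15), Ppbp by 4.90 ± 0.18, Cxcl1 by 4.81 ± 0.23 and Saa3, a serum amyloid gene, by 4.28 ± 0.13 (adjusted p = 1.21e-15). Cxcl2 (4.17), Tnf (3.89), Lcn2 (3.86), which encodes a siderophore-binding protein, and Il1b (3.66) followed. Ffar2, a receptor for short-chain fatty acids, was lower (-3.53 ± 0.13, adjusted p = 1.33e-14), as were the amino acid transporter Slc7a5 (-3.0), Nrep (-2.91), Klf4 (-2.86), Gpr171 (-2.69), Hemk1 (-2.59), Dab2 (-2.51) and Mgarp (-2.49). All went the same way in 6 of 6 combinations. In all, 3274 genes changed at 8 h (1588 higher, 1686 lower), and 444 of them by at least 2-fold (257 higher, 187 lower).

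By group at 8 h, 12 of 14 NF-kB genes were higher by either adjustment, and 18 of 21 inflammatory effectors were higher and 1 lower by either adjustment. Of 17 chemokine genes, 10 were higher and 1, Ccl7 (-1.01), lower (10 and 3 over the list alone). Of 20 cell cycle genes, 13 were lower and none higher by either adjustment, including the centromere histone Cenpa (-1.36), Birc5 (-1.20), Top2a (-1.14) and Cdc20 (-1.0). These 4 lists were called with the preset correlation (adjusted p = 3.81e-09, 4.15e-15, 7.76e-06 and 6.10e-08) and with an estimated correlation (adjusted p = 0.0203, 0.00457, 0.0203 and 0.0399). Of 25 interferon-stimulated genes, 23 were higher (24 adjusted over the list alone), with a median of 1.2 and an adjusted p = 5.94e-10 that became an adjusted p = 0.204 with an estimated correlation. Of 23 maturation genes, 16 were higher and 3 lower (18 and 3 over the list alone), with H2-M2 at 2.54, Cd40 at 2.26, Tnfsf4 at 1.56 and Fscn1 at 1.49. Of 18 cytokine genes, 11 were higher by either adjustment, and of 14 cholesterol biosynthesis genes 8 were higher and 1 lower (9 and 1 over the list alone). Camera adjusted p-values of 4.89e-06, 4.13e-06 and 0.00947 for these 3 lists all became an adjusted p = 0.0921 with an estimated correlation.

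MHC class II, glycolytic and some cell type genes were lower at 8 h. Of 12 MHC class II genes, 6 were lower by either adjustment (adjusted p = 0.00963, and adjusted p = 0.163 with an estimated correlation). Of 16 MHC class I genes, Tapbpl (0.53), Nlrc5 (0.51) and H2-K1 (0.45) were higher and none lower, or 2 higher adjusted over the list alone (adjusted p = 0.0611). Of 16 glycolysis and hypoxia genes, 10 were lower (11 lower and 1 higher over the list alone; adjusted p = 4.00e-04, and adjusted p = 0.179 with an estimated correlation). Conventional dendritic cell markers had 6 of 11 lower and 1 higher, and eosinophil markers had 2 of 5 lower, each by either adjustment and with an adjusted p = 0.0359 and an adjusted p = 0.0921 with an estimated correlation. Both Langerhans-like or migratory cell markers tested, the cadherin Cdh1 (-2.31) and the claudin Cldn1 (-1.23), were lower. Immediate-early genes went both ways, with 6 of 16 higher and 4 lower, and their median of 0.12 opposed their mean of -0.08 (adjusted p = 0.877). The median and mean also had opposite signs for macrophage markers (0.03 and -0.02), neutrophil markers (-0.11 and 0.27) and B cell markers (-0.03 and 0.32), none of which was called.

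At 24 h Saa3 (5.20 ± 0.13, adjusted p = 1.60e-17), Lcn2 (5.0 ± 0.12, adjusted p = 7.18e-18) and Hp (5.0 ± 0.15), which encodes haptoglobin, stood beside Cxcl5 (5.82 ± 0.20) and Ppbp (5.42 ± 0.18). The glutathione transferases Gsta1 (4.88) and Gsta3 (4.86) and the dehydrogenase Adh7 (4.24) were higher too, although a second Gsta3 probe gave 0.18 (adjusted p = 0.132). The aldehyde dehydrogenase Aldh3a1 (-4.10 ± 0.10, adjusted p = 7.18e-18) and the carbonic anhydrase Car4 (-4.06 ± 0.14) fell most, followed by the gluconeogenic enzyme Fbp1 (-3.62), Hemk1 (-3.21), Ffar2 (-3.17), Tcaf2 (-3.08), Prg2 (-3.03) and the lectin Clec10a (-2.88). All went the same way in 6 of 6 combinations. In all, 3374 genes changed at 24 h (1787 higher, 1587 lower), and 501 of them by at least 2-fold (309 higher, 192 lower).

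Inflammatory effectors were higher in 15 of 21 genes and lower in 1 at 24 h (17 and 1 over the list alone), and cell cycle genes were lower in 14 of 20 (15 adjusted over the list alone). Conventional dendritic cell markers were lower in 8 of 11 and higher in 2 (9 and 2 over the list alone), including Mgl2 (-2.20), Irf4 (-1.38), Kmo (-1.21) and Batf3 (-1.17). Eosinophil markers were lower in 3 of 5 by either adjustment. Macrophage and monocyte markers were higher in 6 of 12, including Ms4a7 (2.59), Adgre1 (2.20) and Cd14 (1.79), and lower in 1, Mrc1 (-2.54), or 8 and 2 over the list alone. These 5 lists had adjusted p-values of 6.42e-12, 6.57e-08, 1.37e-04, 0.00219 and 0.011, and of 0.01, 0.0384, 0.01, 0.0371 and 0.0493 with an estimated correlation. The macrophage call was lost with an offset of 16 (adjusted p = 0.0531) and with normexp (adjusted p = 0.0535).

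Interferon-stimulated genes were higher in 23 of 25 at 24 h (25 adjusted over the list alone, median 1.33), NF-kB genes in 8 of 14 by either adjustment, and cytokine genes in 10 of 18 with 2 lower (11 and 2 over the list alone). MHC class II genes were lower in 6 of 12 and higher in 1 (7 and 1 over the list alone), with H2-DMb2 at -1.61 and H2-DMa at -1.57. Camera adjusted p-values of 2.25e-09, 2.26e-05, 4.90e-04 and 6.78e-04 for these lists became adjusted p-values of 0.321, 0.0596, 0.258 and 0.0811 with an estimated correlation. Uncalled lists whose median and mean differed in sign were immediate-early genes (0.12 and -0.06), neutrophil markers (-0.12 and 0.62) and T and natural killer cell markers (-0.02 and 0.06). The heat shock list had a median of 0.05 and a mean of 0.07 with a downward camera direction (adjusted p = 0.880).

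A change from early (0 and 1 h) to late (8 and 24 h) times differed between relb-/- and WT for 18 genes (12 higher, 6 lower), between crel-/-relb-/- and WT for 40 genes (17 higher, 23 lower), and between crel-/-relb-/- and relb-/- for 55 genes (28 higher, 27 lower). This comparison asks whether the change from 0 and 1 h to 8 and 24 h depends on RelB and c-Rel. Genes that respond by 1 h have part of their response counted as early. Oasl2, an interferon-stimulated gene, rose from a geometric mean intensity of 154 to 2129 in WT, from 1476 to 3505 in relb-/- and from 149 to 1649 in crel-/-relb-/- cells, so that its late response in relb-/- was smaller by -2.54 ± 0.46 (adjusted p = 0.0226). Trat1 fell from 175 to 73.2 in WT and from 44.9 to 40.6 in relb-/- cells, a difference of 1.11 ± 0.11 (adjusted p = 7.24e-05), but both relb-/- means lay below the median of all values, where a further fall cannot be seen. The hypoxia-responsive hydroxylase gene Egln3 fell from 1082 to 293 in WT and from 644 to 506 in crel-/-relb-/- cells, a difference of 1.54 ± 0.21 (adjusted p = 9.50e-04). S100a8 rose from 350 to 1874 in WT and from 1609 to 3684 in crel-/-relb-/- cells, a difference of -1.23 ± 0.14 (adjusted p = 2.03e-04). Tnf changed by 0.56 in WT and -0.86 in crel-/-relb-/- cells, a difference of -1.42 ± 0.30 (adjusted p = 0.0401). As an average over genotypes and agents, Tnf had already risen by 4.67 at 1 h, so these changes are not measured from 0 h.

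Besides these, the rule named Gsta1 (1.19), Gsta2 (1.14), Calhm6 (0.98), Robo4 (0.97), Ifna5 (0.90), Pou4f1 (0.89), Lcn8 (0.86), the IgG receptor Fcgr2b (-0.99), Selenbp1 (-0.86), Fcrla (-0.65), Rdm1 (-0.60) and Ms4a8a (-0.59) between relb-/- and WT. Between crel-/-relb-/- and WT it named Scin (1.54), Mgarp (1.30), Il4i1 (0.88), Ednrb (0.87), Eno3 (0.85), Ltf (-1.33), the chemokine Ccl3 (-1.26), Amigo2 (-1.08), Ptx3 (-1.03), Hcar2 (-0.95) and the adhesion molecule Vcam1 (-0.92), among others. The differences between crel-/-relb-/- and relb-/- were led by Oasl2 (2.22), Egln3 (1.95) and Mgarp (1.57) upward, and by Apol7c (-1.52), Tnf (-1.51), Fosb (-1.24) and Vcam1 (-1.19) downward. These genes include the class II transactivator Ciita (-0.99) and Socs2 (-0.99).

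As groups, neutrophil markers had a lower change from early to late times in relb-/- than in WT cells (median -0.30; none of 12 called, 4 lower adjusted over the list alone; adjusted p = 1.52e-05, and 0.00841 with an estimated correlation). They also had a lower one in crel-/-relb-/- than in WT cells (median -0.25; 2 lower, 4 adjusted over the list alone; adjusted p = 3.27e-04, and 0.0293 with an estimated correlation). Glycolysis and hypoxia genes had a higher change from early to late times in crel-/-relb-/- than in relb-/- cells, with a median difference of 0.31 and 3 of 16 higher, or 5 adjusted over the list alone (adjusted p = 7.66e-09, and 0.0256 with an estimated correlation). Against WT their median was 0.16 with 1 higher, or 3 adjusted over the list alone (adjusted p = 2.13e-05, and adjusted p = 0.0629 with an estimated correlation). The other camera calls of late responses were lost with an estimated correlation, among them interferon-stimulated genes between the knockouts (median 0.45, adjusted p = 3.52e-04, then 0.541). Over the 241 late-induced genes as a set, the median difference of induction from WT was 0.03 in both relb-/- (46.5% of genes lower, exact permutation p = 0.765625) and crel-/-relb-/- cells (44.0% lower, exact permutation p = 0.796875, both two-sided).

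Of the genes named, 8 of 16 between relb-/- and WT, 2 of 20 between crel-/-relb-/- and WT and 2 of 20 between the knockouts had an early or late mean below the median of all values, which limits their folds. Others had means only just above it, so their folds may be limited too. Examples are Ltf in WT (50.3 early, 54.2 late), and in crel-/-relb-/- cells Vcam1 (52.8 early, 52.6 late) and Scin (53.0 early). With 0 h alone as the early time, 1 array per genotype, limma called 0, 0 and 2 genes, with 399, 523 and 443 genes at an unadjusted p under 0.05. All 18, 40 and 55 genes called kept their direction there and a median of 96.9%, 98.5% and 97.4% of their difference, while their median standard error went from 0.151, 0.152 and 0.144 to 0.245, 0.235 and 0.239. Without 0 h the 3 counts were 1, 14 and 25, without CpG at 1 h they were 6, 10 and 11, and without Pam3CSK4 at 1 h they were 3, 11 and 15. Of the late conditions, leaving out CpG at 24 h left 10 genes between relb-/- and WT, Pam3CSK4 at 8 h left 11 between relb-/- and WT and 16 between crel-/-relb-/- and WT, and Pam3CSK4 at 24 h left 6 between relb-/- and WT. Other settings gave more genes, namely 57, 108 and 236 with 24 h alone as late, 28 and 96 for the comparisons with WT with 8 h alone as late, and 78 and 95 for those of crel-/-relb-/- with WT and with relb-/- with array weights.

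The genes with the largest differences between CpG and Pam3CSK4 were Cxcl1, Il1b, Cxcl2 and Il1a. Averaged over 1, 8 and 24 h, CpG gave less Cxcl1 (-2.32 ± 0.16, adjusted p = 1.18e-08), Il1b (-2.01 ± 0.14, adjusted p = 2.48e-08), Cxcl2 (-1.97 ± 0.11, adjusted p = 1.32e-09) and Il1a (-1.64 ± 0.16, adjusted p = 1.45e-06) than Pam3CSK4, in 9 of 9 combinations of genotype and time. Phlda1 (-1.26), the collagen-crosslinking enzyme Lox (-1.14), the pattern recognition protein Ptx3 (-1.12) and Il6 (-0.99) were lower with CpG as well. Genes higher with CpG included cyclin D1, Ccnd1 (0.96 ± 0.11, adjusted p = 1.74e-05), the Fc receptors Fcgr4 (0.77) and Fcgr1 (0.70), Ly6e (0.70), C1qb (0.595) and the interferon-induced Ifit2 (1.26 ± 0.32, adjusted p = 0.0421), Phf11d (0.89) and Irgm2 (0.71). Each of these genes had the same sign in at least 8 of 9 combinations. In all, 239 genes differed between the agents (97 higher with CpG, 142 lower), and 11 of them by at least 2-fold (4 higher, 7 lower). The count was 41 without WT arrays, 148 without relb-/- and 108 without crel-/-relb-/- arrays. Ifit2 lost its call without WT (adjusted p = 0.265), without crel-/-relb-/- (0.359), without the array that stood apart (0.0821) and with robust variances (0.159). Phf11d and Irgm2 lost theirs in the same 4 settings, and Fcgr1 (0.111), Ly6e (0.0526), C1qb (0.0611) and Il6 (0.0687) lost theirs without WT, Fcgr1 also without crel-/-relb-/- (0.0513).

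The mean difference between agents varied in size between times for several named genes. It is given here over the genotypes (SD, n = 3), and a dependence on time was not tested. At 1, 8 and 24 h it was -3.39 ± 0.66, -1.43 ± 0.13 and -2.15 ± 0.21 for Cxcl1. For Il1b it was -3.10 ± 0.21, -0.88 ± 0.22 and -2.05 ± 0.79, and for Il6 it was -1.98 ± 0.18, -0.18 ± 0.37 and -0.81 ± 0.48. Lox went the other way, from -0.10 ± 0.02 at 1 h to -1.25 ± 0.11 and -2.06 ± 0.17. Ccnd1 was at 0.17 ± 0.11, 1.46 ± 0.51 and 1.24 ± 0.12, and Ifit2 at 0.12 ± 0.15, 2.01 ± 1.75 and 1.63 ± 1.38.

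**Figure D4:**
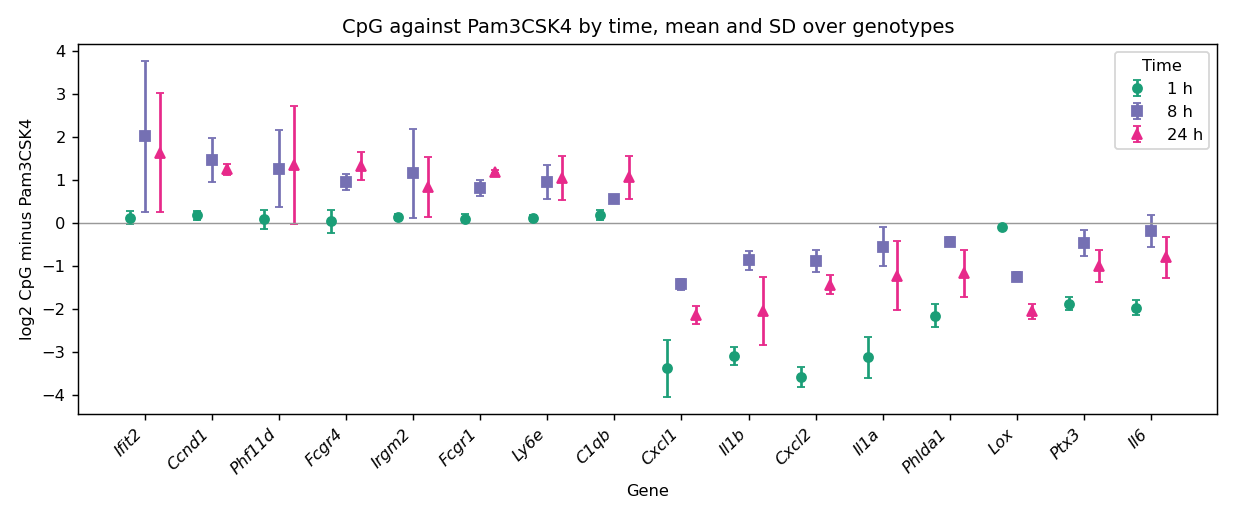
Log2 difference between CpG and Pam3CSK4 for named genes at 1, 8 and 24 h, with the mean over genotypes and its SD (n = 3). Cxcl1 lay at -3.39 at 1 h, and Lox went from -0.10 at 1 h to -2.06 at 24 h.

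By group, inflammatory effectors were lower with CpG in 10 of 21 genes and higher in 1 (14 and 1 over the list alone), including the protease inhibitor Slpi (-0.84), Saa3 (-0.79), the lectin Clec4e (-0.74) and Tlr2 (-0.61). Cell cycle genes were higher with CpG in 5 of 20 (11 adjusted over the list alone), with Mcm5 (0.37), Mcm4 (0.27) and Mcm3 (0.21) of the replicative helicase, Birc5 (0.24) among them. These lists had adjusted p-values of 1.50e-13 and 2.32e-10, and of 0.00803 and 0.0304 with an estimated correlation. Interferon-stimulated genes had a median of 0.54 and 4 of 25 higher with CpG, Ifit3 (1.56), Ifit2, Igtp (0.73) and Oas2 (0.49), or 20 adjusted over the list alone. Of 16 MHC class I genes 1 was higher, or 10 adjusted over the list alone, and of 14 NF-kB genes 3 were lower, or 5 adjusted over the list alone. Camera adjusted p-values of 1.50e-13, 5.76e-08 and 2.19e-06 for these lists became adjusted p-values of 0.266, 0.119 and 0.0741 with an estimated correlation. Cytokine genes (1 of 18 higher, 5 lower; 3 and 8 over the list alone) and maturation genes (1 of 23 higher; 8 higher and 1 lower over the list alone) had adjusted p-values of 0.0112 and 0.00381, which became adjusted p-values of 0.419 and 0.319 with an estimated correlation. Chemokines had 5 of 17 lower and 1 higher with CpG (5 and 3 over the list alone), and neutrophil markers 3 of 12 lower by either adjustment. Their medians (0.09 and 0.01) opposed their means (-0.21 and -0.12), with adjusted p-values of 0.206 and 0.0773.

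No gene's genotype effect was called different between CpG and Pam3CSK4. In limma 0 genes passed for relb-/- against WT and 0 for crel-/-relb-/- against WT, with 245 and 462 genes at an unadjusted p under 0.05 and smallest adjusted p-values of 1.00 and 0.961. In crel-/-relb-/- cells the camera test with the preset correlation called 4 lists in which no member was called. Interferon-stimulated genes (median 0.98, adjusted p = 3.41e-14), cytokines (0.39, 1.36e-05), maturation genes (0.24, 5.45e-04) and MHC class I genes (0.20, 0.00251) had a more positive difference from WT with CpG. With an estimated correlation these had an adjusted p = 0.525, 0.266, 0.525 and 0.598, and MHC class I genes had an adjusted p = 0.106 without the array that stood apart.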

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

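The late-response models, their gene lists and the named genes were planned before the data were examined. The tests chosen after the results were seen are the relabelling of early and late conditions, the 2-fold limit for the single genes given here, and the test of unnamed probes. Differences in late response between genotypes are given here because the difference between genotypes was itself tested, as an interaction. They numbered 18 genes between relb-/- and WT, 40 between crel-/-relb-/- and WT, and 55 between crel-/-relb-/- and relb-/-. When any 3 of the 7 conditions were called early, 1 of 35 choices, the real one, gave counts as high in each comparison. The highest other count was 0, 3 and 27, so the counts depended on the real choice of early conditions. Genotypes were not swapped in this test, and the 0 and 1 h arrays of a genotype resemble each other. It therefore does not exclude a chance difference between cultures or animals. With 0 h alone as early, 1 array per genotype, 0, 0 and 2 genes passed, although all of the genes called kept their direction and a median of 96.9%, 98.5% and 97.4% of their difference. That fit shares the 0 h and late arrays with the first and has larger standard errors, so it neither repeats nor refutes the calls.

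At 2-fold or more between relb-/- and WT, Gsta1 (1.19), Gsta2 (1.14) and Trat1 (1.11) had a higher change from early to late times and Oasl2 (-2.54) a lower one. These changes are signed, so a higher one can be a smaller fall and a lower one a deeper fall. Trat1 was below the median of all values in relb-/- cells at early and late times, so its value shows only that it had no room to fall there. Gsta1 and Gsta2 started below that median in every genotype, so their folds are taken against background. Between crel-/-relb-/- and WT, Scin (1.54), Egln3 (1.54) and Mgarp (1.30) had a higher change, and Tnf (-1.42), Ltf (-1.33), Ccl3 (-1.26), S100a8 (-1.23), Amigo2 (-1.08) and Ptx3 (-1.03) a lower one. Egln3 and Mgarp fell less in crel-/-relb-/- than in WT cells, and Amigo2 fell more. Between crel-/-relb-/- and relb-/-, Oasl2 (2.22), Egln3 (1.95), Mgarp (1.57), Selenbp1 (1.24) and Scin (1.03) had a higher change, and Apol7c (-1.52), Tnf (-1.51), Fosb (-1.24), Vcam1 (-1.19), Jdp2 (-1.10) and Hamp (-1.10) a lower one. Egln3, Mgarp and Selenbp1 fell less in crel-/-relb-/- than in relb-/- cells, and Fosb fell more. Fosb fell below that median in both knockouts, and Hamp started below it in crel-/-relb-/- cells. Only just above it lay Ltf in WT (50.3 early, 54.2 late), and in crel-/-relb-/- cells Vcam1 (52.8 early, 52.6 late) and Scin (53.0 early). Among lists called with both correlations, neutrophil markers had median differences from WT of -0.30 in relb-/- and -0.25 in crel-/-relb-/- cells. Glycolysis and hypoxia genes had a median difference of 0.31 between crel-/-relb-/- and relb-/- cells.

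Probes without a listed gene were outside every comparison of named genes. Of 1719 such probes, 933 passed the brightness filter. In limma 109 of them differed between relb-/- and WT, 139 between crel-/-relb-/- and WT, and 168 between crel-/-relb-/- and relb-/-. With stimulation 14 changed at 1 h, 248 at 8 h and 252 at 24 h, and 15 differed between CpG and Pam3CSK4. The genes they measure are not given in the sources used here.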

How the results depend on the processing

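The relabelling of conditions, the normexp treatment, the removal of the crel-/-relb-/- array at 24 h with CpG and the set of late-repressed genes were tests chosen after the results were seen, and the other alternatives were planned. Named genes were scored in every alternative other than the 2-fold threshold and the test of every probe. Some of them, such as Stat4, Cd40 and Gsta3, had other probes that were not called. The named genes of the genotype comparisons (25, 25 and 24), of 8 h (16) and of 24 h (16) kept their calls and directions in every alternative scored. Of 16 named at 1 h 11 did so, and of 16 between the agents 9. Of the named late responses 0 of 16, 0 of 20 and 1 of 20 did, and 16, 20 and 18 of them lost their call with 0 h alone as early. Among tests of lists 1504 stayed on their side of the threshold, 67 lost a call and 13 gained one, and most losses came with the estimated correlation. Every model compares groups within conditions or genotypes, and the labels give no replicate numbers that could tie arrays to a culture. Brightness limits all folds, as background was left in the values.

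Requiring a 2-fold change left 53, 49 and 93 genes in the genotype comparisons, 32, 444 and 501 at 1, 8 and 24 h, 11 between the agents, and 4, 9 and 11 for late responses. With array weights 261 genes changed at 1 h, and late responses differed for 78 (crel-/-relb-/- and WT) and 95 genes (crel-/-relb-/- and relb-/-). Without the array that stood apart 183 genes changed at 1 h, and with only the 9 arrays compared 362 did. With only the 2 genotypes compared these late responses numbered 12 and 19. With 0 h alone as early the 3 late counts were 0, 0 and 2. With 8 h alone as late they were 28 and 96 for the comparisons with WT, and with 24 h alone 57, 108 and 236. With 0 h alone as early the differences kept their direction and most of their size while standard errors grew. The 2-fold counts are stricter by construction, the array weights use all 21 arrays, and the cause of the other changes was not tested.

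Leaving out 1 condition gave 830 to 1226 genes between relb-/- and WT, 1211 to 1777 between crel-/-relb-/- and WT, and 1612 to 2147 between the knockouts. Late responses ranged from 1 to 20, from 10 to 44 and from 11 to 82 genes. Leaving out 1 genotype gave 30 to 71 genes at 1 h, 2215 to 2829 at 8 h, 2290 to 2922 at 24 h and 41 to 148 between the agents. The agent interactions stayed at 0 in every alternative run with limma, against 245 and 462 genes at an unadjusted p under 0.05.

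The median difference of late induction, 0.03 in both knockouts, was not called under any alternative and had no settled direction. It ranged from -0.03756 (without Pam3CSK4 at 24 h) to 0.07044 in relb-/- and from -0.08707 (without CpG at 24 h) to 0.08383 in crel-/-relb-/- cells when 1 condition was left out, and was -0.07217 in crel-/-relb-/- cells without the array that stood apart. For late-repressed genes the difference in crel-/-relb-/- cells, -0.03, ranged from -0.04827 (without Pam3CSK4 at 1 h) to 0.01383 (without 0 h) when 1 condition was left out. It was 0.01361 without CpG at 24 h, 5.836e-04 without Pam3CSK4 at 24 h and 0.02179 without the array that stood apart. In relb-/- cells the late-repressed difference of -0.15 lost its call without Pam3CSK4 at 24 h (-0.15, exact p = 0.09375) and with conditions relabelled (exact p = 0.0857). With 0 h alone as early it was -0.17, and the exact p = 0.0625 is the smallest possible with 5 conditions, so no call could be made there for either set. The cause was not tested.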

Other observations

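Several gene groups of crel-/-relb-/- cells are not described above. Against WT, 5 of 12 macrophage and monocyte markers were higher by either adjustment, including Fcgr3, the efferocytosis receptor Mertk (0.72), Mrc1 (0.60) and Adgre1 (0.57), and Cd14 (-0.35) and Lyz2 (-0.18) were lower (camera adjusted p = 0.124). The mean of this list was higher in 7 of 7 conditions (0.23, exact permutation p = 0.015625, two-sided, the smallest possible). Inflammatory effectors went both ways, with Saa3 (-1.09) and Clec4e (-0.45) among 4 of 21 lower and Slpi (0.39) and Clec4d (0.31) higher (5 and 4 over the list alone; adjusted p = 0.485). In the cell cycle list Cenpa (0.82), the sliding clamp Pcna (0.63) and Tpx2 (0.35) were higher and the thymidylate synthase Tyms (-0.73) lower among 20 genes (4 and 1 over the list alone; adjusted p = 0.285). The stromal list had Vcam1 (-0.79) and Cxcl12 (-0.15) lower of 6 genes by either adjustment (adjusted p = 0.124). MHC class II genes had H2-Eb1 (0.38) higher and H2-DMb2 (-0.61) and H2-DMa (-0.30) lower among 12 (4 and 2 over the list alone; adjusted p = 0.485).

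Between crel-/-relb-/- and relb-/- cells the plasmacytoid markers Tcf4 (-0.82), a transcription factor of that lineage, and Cox6a2 (-0.64) were lower and Ly6d (0.19) higher of 6 genes (3 and 1 over the list alone; adjusted p = 0.270). Neutrophil markers had S100a9 (1.08), Ltf (0.98), S100a8 (0.75) and Ngp (0.52) among 6 of 12 higher, and Lcn2 (-0.50) and Retnlg (-0.32) were lower by either adjustment (adjusted p = 0.0609), and the list's mean was higher in 7 of 7 conditions (0.26, exact permutation p = 0.015625, two-sided). T and natural killer cell markers had Nkg7 (0.61), Cd3d (0.39) and Cd3e (0.22) higher and Prf1 (-0.23) and Klrd1 (-0.19) lower of 7 (adjusted p = 0.132). Between the agents, the complement genes C1qb and C1qc (0.49), Fcgr1 and Mertk (0.37) were higher with CpG, and the lipopolysaccharide co-receptor Cd14 (-0.74) and Adgre1 (-0.31) were lower (adjusted p = 0.0573, and 0.0425 with cyclic loess).

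All explanations and splits of the samples that follow were tested only after the results were seen. Genotype labels were swapped within conditions in 64 ways. In each genotype comparison 1 of the 64, the real one, gave as many genes. The real counts were 1236, 1629 and 2099 and the highest others 138, 574 and 642. As 1 of 64 is the smallest share possible, chance variation between conditions is an unlikely source of these counts. A chance difference between single cultures or animals would be constant over the conditions and would pass this test, so it is not excluded. Within the 9 arrays of a time and 0 h, 1 of 27 swaps, the real one, gave as many genes, with 362, 3512 and 2727 at 1, 8 and 24 h and highest others of 262, 1477 and 1163. For the agents 1 of 100 swaps, the real one, gave 239 genes, and the highest other gave 96. Chance in which arrays of a genotype carried which label is thus an unlikely source of these counts. The agent interactions allow only 10 splits, too few for a share under 0.05. All 10 gave at least the real count of 0 in both, and the highest other counts were 0 and 1.

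Interferon-stimulated genes were higher in relb-/- than in WT cells, with a median of 1.08 and an SD over members of 0.728. RNA from plasmacytoid dendritic cells would raise their markers alongside, and 5 of these other than Bst2, itself induced by interferon, had a median difference of -0.00306 (SD 0.211, highest 0.308). For these 5 markers this argues against such RNA as the main source. Only markers above the brightness filter were tested, and the brightest of these 5 averaged an intensity of 459. Other listed markers were not tested, so they could not show such RNA. Whether interferon secreted by a few such cells raised the list was not tested. The list already differed by 1.47 between the unstimulated arrays, with 1 array per genotype, so a difference between cultures or animals other than Relb cannot be told apart from the genotype. In crel-/-relb-/- cells, which lack RelB too, the list's mean difference from WT was -0.22 on the unstimulated arrays. It was above 0 in 2 of 7 conditions, at 8 h (0.70) and 24 h (0.865) with CpG, the latter from the array that stood apart. Single arrays that go both ways do not show whether loss of RelB is enough to raise these genes. A restraint by RelB that matters only while c-Rel is present is left as a hypothesis, which replicate cultures would be needed to test.

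Genes beside the disrupted loci may differ because DNA of the strain in which an allele was made was carried along, and that strain is not given in the sources used here. Among 10180 windows of 20 neighbouring tested genes, 3.40% changed as much as the neighbours of Relb in relb-/- against WT, 2.76% in crel-/-relb-/- against WT, and 29.8% between the knockouts, taken here to carry the same Relb allele. Carried DNA could give these shares, and local effects of the disruption itself were not tested. For Rel the shares were 5.64% in crel-/-relb-/- against WT, 21.7% between the knockouts and 88.6% in relb-/- against WT, so carried DNA cannot be told apart from chance there with 20 genes. Genes picked after their values were seen are Clasrp, next to Relb (-1.11 and -0.83 against WT), Pus10, next to Rel (-1.34 in crel-/-relb-/- cells), and Crxos, on chromosome 7 with 53 tested genes between it and Relb (2.08 and 2.79). Zfp296, Pvr and Apoc2, near Relb, were picked after as well. Between the knockouts Zfp296 (-0.655), Pvr (-0.528), Crxos (0.70) and Clasrp (0.28) were called different, and Apoc2 (0.07) was not. A carried segment shared by both knockouts would not by itself give such differences. Fcgr3 and Ifi202b, both on chromosome 1 and also picked after, had shares of 2.38% and 2.96% in crel-/-relb-/- against WT, 4.88% and 0.982% between the knockouts, and 49.6% and 1.41% in relb-/- against WT, and as families of related genes lie there, carried DNA cannot be told apart from an effect of genotype on them.

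Maturation genes were lower in crel-/-relb-/- than in WT cells (median -0.30). The array that stood apart does not account for this, since the median was -0.34 without it. A lower share of dendritic cells could lower their markers together, but 23 conventional dendritic cell and MHC class II genes had a median of 0.0314 (SD 0.342), with 3 higher and 6 lower. Members that go both ways decide little, so a change in the mixture of cells cannot be told apart from lower maturation. A need for c-Rel in maturation is the biological hypothesis, which replicate cultures and cells that lack only c-Rel would be needed to test.

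A hypothesis from these data was that genes repressed late fall further without RelB. Over 144 such genes the median difference from WT was -0.15 in relb-/- cells, with 71.5% of genes lower. The exact permutation p was 0.015625, the smallest possible, when genotypes were swapped, but swaps also move the constant difference between genotypes, and the exact p was 0.0857 when conditions were relabelled, so this may be chance. In crel-/-relb-/- cells the median was -0.03 (exact p = 0.75). Another hypothesis was that interferon-stimulated genes of crel-/-relb-/- cells differ more from WT with CpG than with Pam3CSK4. The mean difference between agents was 0.944, with an exact p = 0.1 (two-sided), the smallest possible with 3 conditions against 3, so the design cannot decide. This difference includes the crel-/-relb-/- array at 24 h with CpG, which stood apart.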
